A study of Homo sapiens with 10 samples.

How the data were processed

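Total RNA from 10 clear cell renal cell carcinoma tumours was depleted of ribosomal RNA and made into libraries with an Ion Torrent kit from 100 ng, per the labels. The authors deposited raw counts of reads per gene symbol in 1 table with 1 column per tumour. The submitters' notes name HTSeq 0.5.4, Picard, limma and the build hg19 (GRCh37), with no role or order; the aligner and annotation are not given in the sources used here. Of 51006 table entries per tumour, 5 had the form of HTSeq summaries and were left out of library totals and tests. Reads in more than 1 gene made up 4.51% to 9.15% of uniquely aligned reads, reads outside genes 13.6% to 40.7%, and alignments that were not unique 39.8% to 59.7% of all entries summed. Reads outside genes are those assigned to no feature. The type of feature counted is not given, so they may include reads in introns of genes. Of 51001 genes, 27 carried names that a spreadsheet had turned into dates; they were counted but never named. Each tumour is 1 library, so the p-values of relations, pairs and slopes measure the spread between tumours. Those of list variability and coherence compare lists of genes within the same libraries. Gene totals of 21539248 to 38151561 and a common biological coefficient of variation of 68.2% set the precision.

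Counts were scaled with TMM factors, genes with a mean count of at least 10 were kept, and log2 CPM used a prior count of 2. Genes of chromosome Y, XIST, TSIX and genes of common inherited deletions or haplotypes were left out of tests and tables, which left 21229 genes. Merged exon lengths from GENCODE release 29 (GRCh38) were matched by symbol or synonym for 30668 genes; no coordinate was used, since the authors' build differs. Genes without a match were counted but not named.

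Chosen before the data were examined were 28 lists (358 genes, 356 in the table), 24 gene pairs, 22 relations between lists, the tests and the genes to name. These are from each list the 2 members of highest mean CPM, the most variable and the lowest; any member of the glutathione synthesis, gamma-glutamyl cycle, glutathione use, HIF target and glycolysis lists; the 15 genes with the highest share of counts; the 15 most variable genes with a mean of at least 10 CPM; for each score the 10 genes of smallest p in each direction past the threshold, or named as not past it; and the genes of the pairs. A gene outside this rule is given as chosen after its values were seen.

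A list score was the mean z-score of log2 CPM over members. Relations used Pearson's r and Spearman's rho with two-sided permutation tests, of 100000 resamples at n = 10 and exact below; a second term was removed from both scores by regression before the test. Pairs used a pseudocount of 0.5 and a two-sided exact sign-flip permutation test. Slopes used the quasi-likelihood test of edgeR 4.0.16 on the score scaled to an SD of 1, with SEs derived from the F statistic and members of the score left out of counts; limma 3.58.1 (voom) and DESeq2 1.42.0 were alternatives, in R 4.3.3. Variability was the median residual of log2 variance from a lowess trend (two-sided) and coherence the mean pairwise r of members (one-sided), each against 10000 random lists matched in 20 bins of expression. Benjamini-Hochberg adjustment was made within each family, with a threshold of 0.05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

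The tests were tested on simulated data. For the glutathione score 0%, 32%, 60% and 72% of 50 genes were recovered at slopes of 0.5, 1, 1.5 and 2 log2 units per SD, with 1 false call among 21029 genes; for the HIF score these were 0%, 32%, 60% and 82%, with 2 false calls. The variability test called 20 of 20 lists of doubled SD, 0 of 20 uncorrelated and 5 of 20 correlated lists of unchanged SD. A version with correlated random lists, added for this reason, called 20, 0 and 0. The coherence test called 20 of 20 correlated lists and 1 of 40 others. At a true correlation of 0, 69 of 1000 simulated relations had a p under 0.05, and at a mean ratio of 0, 55 of 1000 pairs did.

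Alternatives chosen beforehand were DESeq2 size factors, library totals only, other filters, prior counts and pseudocounts, no length correction, other tools and statistics, the proximal tubule score or log2 library total as a second term, unscaled scores, totals without mitochondrial and nonpolyadenylated genes, removal of the first component, and leaving out each tumour. Chosen after the data were seen were the 7 tumours with under 25% of uniquely aligned reads outside genes, that share or the macrophage score as a second term, correlated random lists, and the relations of scores and components to the share. For each slope count the score was also permuted over the tumours, first 40 times and, after those counts were seen, 99 times; both are given.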

Results

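RNA from 10 clear cell renal cell carcinomas, a kidney cancer marked by loss of the VHL tumour suppressor, was sequenced after depletion of ribosomal RNA. The labels give 1 group of 10 tumours, and the design text places them in a cluster with high glutathione, a thiol antioxidant. Tumours of other clusters and normal kidney were not analysed here, so no level below is high or low against another kind of sample. What can be described are gene levels, ratios of genes within a tumour, and covariation over the 10 tumours, whose numbers are only names. Reads counted in genes ranged from 21539248 to 38151561 per tumour, with a mean of 31560146 ± 5751698 (SD, n = 10). Uniquely aligned reads assigned to no feature are called reads outside genes here, though they may include reads in introns. They made up 40.7% of uniquely aligned reads in tumour 1, 34.9% in tumour 5 and 31.3% in tumour 8. In the other 7 tumours this share lay between 13.6% and 21.1%.

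**Figure D1:**
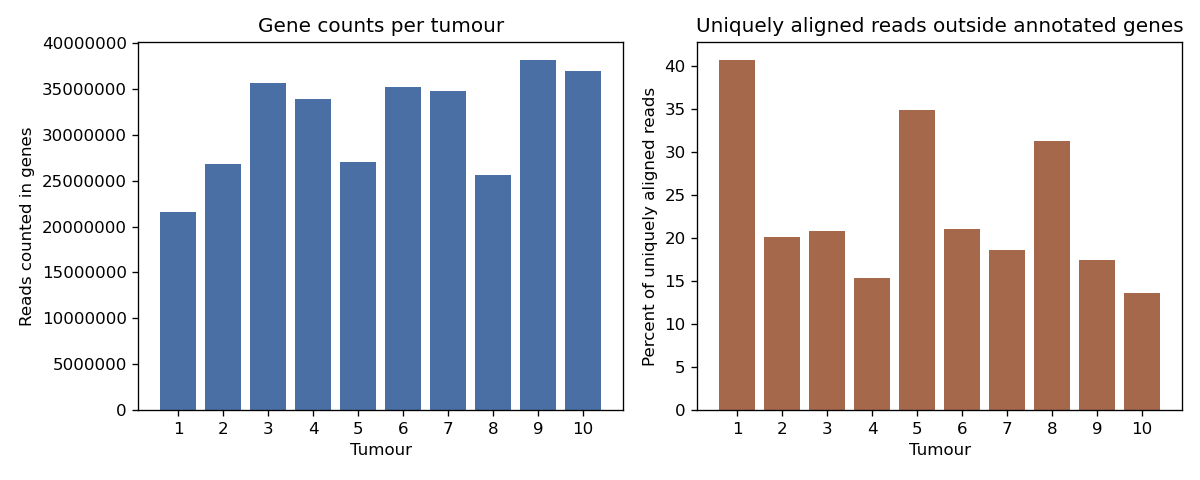
Reads counted in genes (left) and reads outside genes as a percent of uniquely aligned reads (right), with 1 bar per tumour. Reads outside genes are those assigned to no feature and may include reads in introns. Tumours 1, 5 and 8 have the 3 highest shares outside genes, 40.7%, 34.9% and 31.3%.

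Targets of hypoxia-inducible factor (HIF), the transcription factor that VHL marks for degradation, stood high in the ranking of transcripts. Their 17 genes had a median percentile of 97.7 among genes ranked by read counts scaled to the library total (CPM) per kilobase of exon. VEGFA, a growth factor for blood vessels, averaged 4019 CPM ± 3075 (SD, n = 10), NDRG1 1907 ± 999.7, ANGPTL4 1525 ± 1126, CA12 942.8 ± 399 and NDUFA4L2 720.2 ± 418. ANKRD37 was the lowest, at 5.65 ± 3.12. The 16 glycolysis genes had a median percentile of 98.4, with GAPDH at 4288 CPM ± 1711, ENO1 at 1653 ± 1006 and PKM at 1620 ± 849.8.

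The 5 genes of glutathione synthesis had a median percentile of 46.7. GCLC and GCLM, the subunits of the rate-limiting ligase, averaged 22.5 CPM ± 12.8 and 16.9 CPM ± 4.95 (SD, n = 10). GSS, the enzyme of the last step, averaged 102 CPM ± 35.6, and the cystine transporter subunits SLC7A11 and SLC3A2 averaged 3.62 ± 1.88 and 163 ± 67.4. Genes that use glutathione had a median percentile of 79.4, led by GPX3, a secreted peroxidase, at 2192 CPM ± 1113, with GSTK1 at 361 ± 107 and GPX2 lowest at 1.25 ± 1.38 (0.832 without tumour 1). The gamma-glutamyl cycle, which breaks glutathione down, had a median percentile of 67.7, with ANPEP at 433 CPM ± 218 and CHAC2 at 0.734 ± 0.235. Targets of NRF2, the regulator of the oxidative stress response, had one of 74.7, with FTL at 3880 CPM ± 3945 and HMOX1 at 409 ± 515 (251 without tumour 4).

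Among other metabolic lists, nuclear oxidative phosphorylation genes had a median percentile of 93.8 (ATP5B 569 CPM ± 283, SD, n = 10) and tricarboxylic acid (TCA) cycle genes 86.8 (SDHA 222 ± 141). The pentose phosphate list had one of 84.4 (TKT 153 ± 42.5), arginine and polyamines 78.8 (SAT1 696 ± 345), fatty acid oxidation 75.6 (ACADVL 1225 ± 447) and lipid storage and synthesis 75.3 (PLIN2, which coats lipid droplets, 806 ± 514). Kynurenine and nicotinamide genes had one of 72.0 (NNMT 1274 ± 616) and one-carbon and methionine genes 68.4 (MAT2A 278 ± 132). Mitochondrially encoded genes took 4.30% to 27.6% of gene counts; MT-ND4 alone averaged 1.78% ± 1.57.

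Markers of other cell types were present at different levels. Stroma had a median percentile of 97.6 (SPARC 2417 CPM ± 1322, SD, n = 10), macrophages 97.5 (C1QB 496 ± 355), endothelium 93.6 (VWF 1249 ± 1163) and erythroid cells 92.4 (HBB 185 ± 304, and 94.6 without tumour 10). T and cytotoxic cells had one of 78.3 (CCL5 171 ± 138), proximal tubule 75.9 (AQP1 383 ± 352), B and plasma cells 61.2 (IGJ 44.7 ± 89.3, and 16.7 without tumour 2) and other nephron segments 7.83 (NPHS1 7.60 ± 22.9, and 0.360 without tumour 1). Antigen presentation genes had one of 98.3 (CD74 5457 ± 2116), immediate early genes 97.2 (DUSP1 1913 ± 1419), nonpolyadenylated RNAs 88.4 (MALAT1 4268 ± 4444), 3p tumour suppressors 62.5 (BAP1 94.6 ± 19.1) and proliferation genes 49.4 (MKI67 48.1 ± 23.1). Reads of genes with near-identical copies or overlapping neighbours are not counted, so the levels of such genes are uncertain. Examples are PGAM1 (13.3 CPM), MRC1 (0.183 CPM, 0.116 without tumour 4) and the globins HBA1 and HBA2. Other list members were not screened for this and may be affected too.

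Within each tumour, 24 pairs of isoenzymes or related genes were compared per kilobase of exon. The first gene was higher in 15 pairs, the second in 4, and 5 did not pass the test. NDUFA4L2, a HIF target, exceeded its relative NDUFA4 13.7-fold (mean log2 ratio 3.78 ± 0.99, SD, n = 10), and EPAS1, which encodes HIF-2 alpha, exceeded HIF1A 5.25-fold (2.39 ± 0.81). SLC2A1 exceeded SLC2A2 53.8-fold, PFKP exceeded PFKM 12.6-fold, GPX3 exceeded GPX1 9.33-fold and VIM exceeded CDH1 64.4-fold. In the other direction COX4I1 exceeded COX4I2 4.08-fold, HK1 exceeded HK2 2.71-fold, IDH2 exceeded IDH1 4.41-fold and PDK4 exceeded PDK1 24.9-fold. Each of these held in 10 of 10 tumours, with an adjusted p of 0.00293 over the 24 pairs. That came from a p of 0.00195, the smallest that a two-sided exact sign-flip permutation test of 10 tumours can give. The test measures only how constant a ratio is over tumours. A bias of 1 gene present in all libraries, from uncounted reads or exon length, would pass it too. The pairs were not screened for such bias, and the ratios cover all cell types in a piece. LDHA exceeded LDHB 1.60-fold in 9 of 10 tumours (adjusted p = 0.0493, exact permutation test), a call that passed without tumour 1 alone. Its adjusted p was 0.0987 without tumour 2, 8 or 9, 0.0656 without 3, 0.0740 without 4, 0.0543 without 5, 0.0563 without 6, 0.0641 without 7 and 0.0893 without 10. FABP7 exceeded FABP1 in 8 of 10 tumours (adjusted p = 0.0156, exact permutation test). That pair did not pass by the exact sign test (adjusted p = 0.131) or within the 7 tumours of low share outside genes (adjusted p = 0.118, exact permutation test). GCLC and GCLM did not differ beyond the spread between tumours (mean log2 ratio -0.41 ± 1.10, adjusted p = 0.310, exact permutation test). The same held for PCK2 and PCK1 (adjusted p = 0.0680), MTHFD2 and MTHFD1 (0.709), GSTP1 and GSTA1 (0.533), and CA9 and CA12 (0.914), by the exact permutation test. PCK2 was higher than PCK1 without tumour 3 or 6 (adjusted p = 0.0197 and 0.0444) and GSTP1 higher than GSTA1 without tumour 10 (0.0296, exact permutation test). CA9/CA12 turned to a positive mean log2 ratio without tumour 1 (0.20), 5 (0.00602) or 10 (0.14), and MTHFD2/MTHFD1 without tumour 9 (0.0203), none past the threshold. Without length correction the adjusted p was 0.00740 for MTHFD2/MTHFD1, 0.0384 for GSTP1/GSTA1 and 0.00335 for CA9/CA12 (exact permutation test). The size of other ratios moved too, with mean log2 ratios of -4.82 against -2.03 for COX4I2/COX4I1, -2.92 against -4.64 for PDK1/PDK4, -1.39 against -2.14 for IDH1/IDH2, 4.37 against 3.22 for GPX3/GPX1, 3.05 against 3.65 for PFKP/PFKM and 1.74 against 0.68 for LDHA/LDHB.

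**Figure D2:**
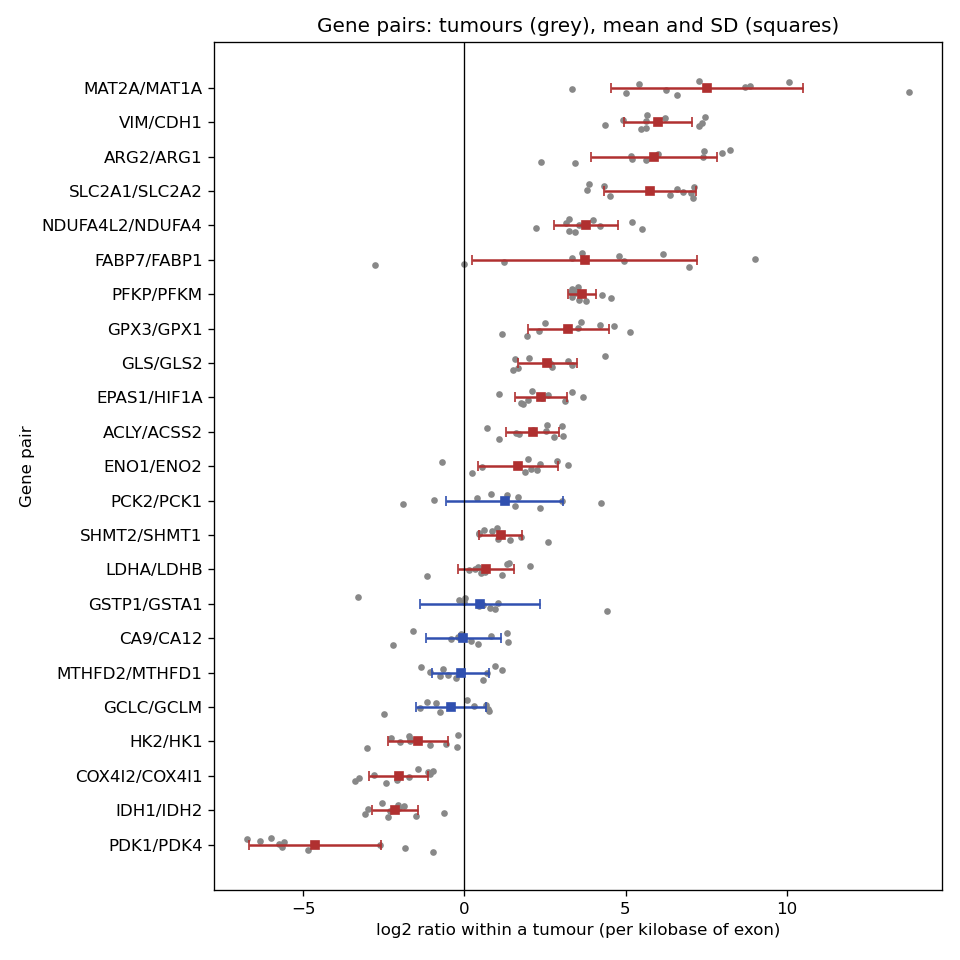
Log2 ratio of the first to the second gene of 23 of the 24 pairs within each tumour (horizontal axis, per kilobase of exon), with grey points for tumours and squares with bars for the mean ± SD. Red squares mark the 18 pairs shown that passed the threshold and blue squares the other 5; NDUFA4L2/NDUFA4 averages 3.78 and PDK1/PDK4 averages -4.64.

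Proximal tubule, lipid storage, erythroid, B and plasma cell, and immediate early genes varied more between tumours than random lists matched on expression, in each alternative run. SLC22A6, an organic anion transporter of the proximal tubule, ranged from 0.102 to 164 CPM, and FABP7, a fatty acid binding protein, from 0.0785 to 515 CPM. The mean of FABP7 was 4.96 CPM without tumour 6. In all, 13 of 28 lists passed and 0 were less variable than random lists. That test also called 5 of 20 simulated lists that were correlated but not more variable. With random lists given each list's own correlation, 9 of 28 passed: those 5 and stroma, HIF targets, kynurenine and nicotinamide, and other nephron genes. NRF2 targets (adjusted p = 0.0896), T cells (adjusted p = 0.0682), macrophages (adjusted p = 0.0504) and endothelium (adjusted p = 0.108) did not pass with that correlation. Within the 7 tumours of low share outside genes, HIF targets (adjusted p = 0.202), other nephron genes (0.542) and endothelium (0.0774) did not pass. The adjusted p was also above 0.05 for HIF targets (0.0933), other nephron genes (0.0797) and endothelium (0.0565) without tumour 1, for endothelium without tumour 2 (0.0569), and for kynurenine and nicotinamide (0.0616), macrophages (0.0565) and stroma (0.117) without tumour 3. With genes of a mean count of at least 50 it was 0.0854 for NRF2 targets, 0.190 for kynurenine and nicotinamide and 0.523 for other nephron genes, and with a prior count of 0.5 it was 0.0556 for NRF2 targets. Glutathione synthesis did not stand apart from random lists (adjusted p = 0.946). All these p-values compare lists of genes within the same libraries, where genes are not independent replicates, and do not measure the spread between tumours.

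Members of 23 of 28 lists rose and fell together over the tumours more than members of random lists. Their mean pairwise correlation was 0.731 for macrophage genes, 0.746 for B and plasma cell genes, 0.710 for glycolysis, 0.525 for HIF targets and 0.400 for NRF2 targets. It was 0.176 for glutathione synthesis (adjusted p = 0.131), so that score averages genes that did not covary detectably. Glutathione use (adjusted p = 0.0999), the gamma-glutamyl cycle (0.526), kynurenine and nicotinamide (0.192) and 3p tumour suppressors (0.0587) did not pass either. The 3p tumour suppressors did pass in 6 of 19 alternatives. Of the 23, nuclear oxidative phosphorylation did not pass without tumour 7 or 8 (adjusted p = 0.0552 and 0.0570), other nephron genes without tumour 1 (0.290), antigen presentation without tumour 8 (0.0975) and stroma without tumour 3 (0.114). Within the 7 tumours one-carbon and methionine (0.288), fatty acid oxidation (0.0652), other nephron genes (0.125) and antigen presentation (0.339) did not pass. Arginine and polyamines (0.0515), one-carbon and methionine (0.113) and fatty acid oxidation (0.113) did not with the first principal component removed, nor arginine and polyamines (0.0522) with the share of reads outside genes as a second term. Genes are not independent replicates, so these values describe lists in these libraries only.

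**Figure D3:**
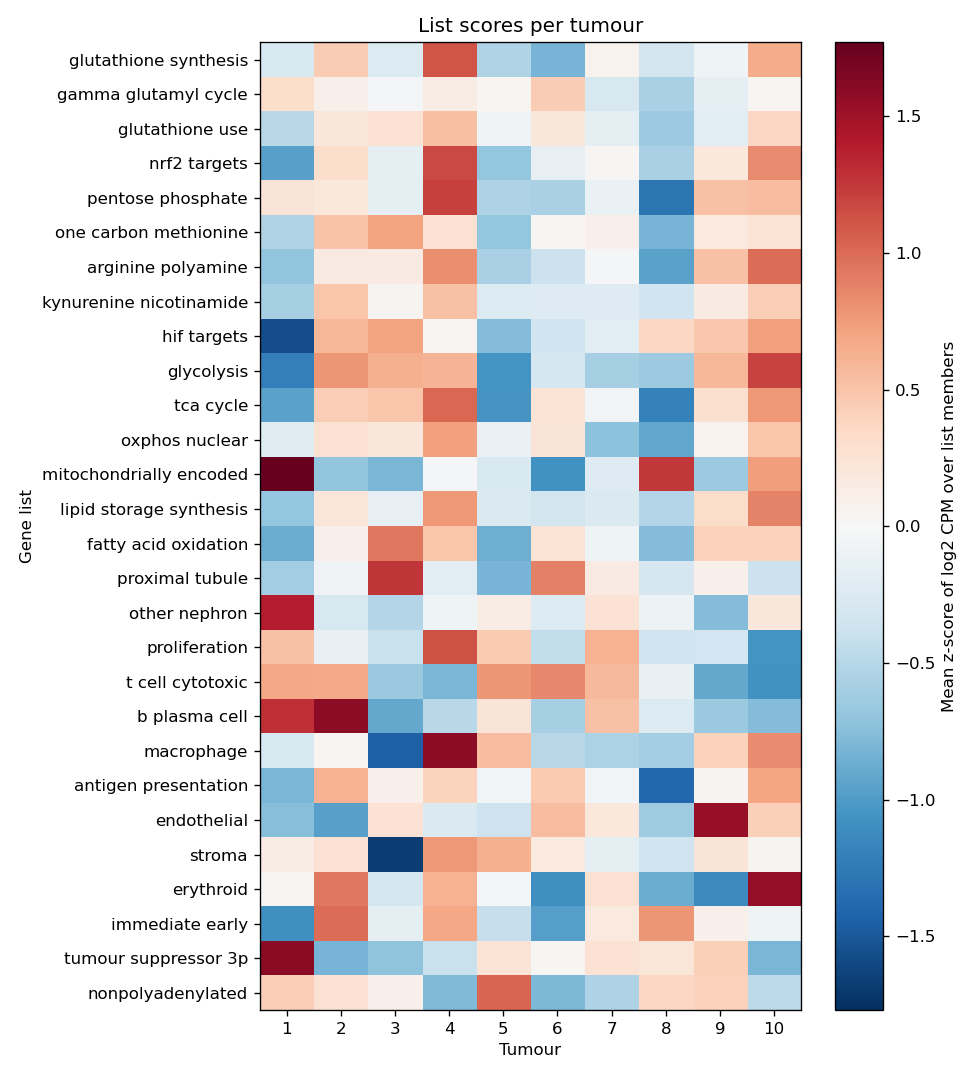
Score of each of 28 gene lists (vertical axis) in each of 10 tumours (horizontal axis), as the mean z-score of log2 CPM over members; red is above and blue below the mean of the tumours. Tumour 1 has the highest other nephron score, 1.39, and a HIF target score of -1.58.

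The main axis of variation over all genes followed the share of reads outside genes. The first principal component held 29.9% of the variance, and its absolute r with the share was 0.978 (permutation p = 9.0e-05; rho = 0.891, permutation p = 0.00125; n = 10). The absolute r was 0.939 without the 2 tumours farthest from the median share (exact permutation p = 0.00439) and 0.744 within the 7 tumours of low share. Scores of 12 of 28 lists followed the share after adjustment over the 28 (permutation test). NRF2 targets (r = -0.893, rho = -0.939, permutation p = 0.000160 for rho) and arginine and polyamines (-0.857, rho = -0.927, p = 0.000330) fell with it, with r of -0.863 and -0.917 within the 7 tumours. The TCA cycle (-0.908, rho = -0.794, permutation p = 0.00811) and glycolysis (-0.848, rho = -0.782, p = 0.0105) fell with it, with r of -0.617 and -0.513 within the 7. HIF targets (-0.751, rho = -0.661, permutation p = 0.0431) and 3p tumour suppressors (0.732, rho = 0.430, p = 0.220) had r of -0.236 and 0.131 within the 7. Without tumours 1 and 5, the 2 farthest from the median share, theirs was -0.0601 and 0.359 (exact permutation p = 0.904 and 0.427), so these 2 relations rest on those tumours. Fatty acid oxidation (-0.861, rho = -0.733, permutation p = 0.0201) and one-carbon and methionine (-0.795, rho = -0.636, p = 0.0538) had -0.704 and -0.691 without tumours 1 and 5 (exact permutation p = 0.0752 and 0.101), so the call rests on those tumours but the size of r does not. Within the 7, without tumour 8 as well, theirs was -0.0345 and 0.252. The other 4 were lipid storage (-0.792), kynurenine and nicotinamide (-0.798), glutathione use (-0.720) and antigen presentation (-0.731), with -0.898, -0.583, -0.329 and -0.309 within the 7. Glutathione synthesis did not pass by r (-0.582, permutation p = 0.0762, adjusted p = 0.142), with rho = -0.830 (permutation p = 0.00477). These relations were chosen after the data were seen.

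The glutathione synthesis score rose with the NRF2 target score over the 10 tumours, 1 of 2 relations that passed among 22 between list scores. Its r was 0.844 (permutation p = 0.00212, adjusted p = 0.0233) and its rho 0.830 (permutation p = 0.00488). The 2 lists share no gene, but GCLC, GCLM and SLC7A11 of the glutathione synthesis list are themselves known NRF2 targets. The 2 scores are therefore not independent by design. Not each member of the glutathione synthesis score followed: GCLM was highest in tumour 1 (24.9 CPM), where the NRF2 target score was lowest (-0.967). Without the 2 tumours farthest from the median glutathione score, 4 and 10, r was 0.554 (exact permutation p = 0.155), so the relation rests on those tumours. It was 0.925 within the 7 tumours of low share outside genes (exact permutation test, adjusted p = 0.0306), 0.887 given that share (permutation test, adjusted p = 0.0117) and 0.743 given the macrophage score (permutation test, adjusted p = 0.0614). All 14 NRF2 targets had positive slopes on the glutathione score; 7 passed when adjusted over the list alone and 0 over all genes tested (edgeR quasi-likelihood test). The 7, named after their values were seen, were TXNRD1, SRXN1, HMOX1, ME1, PRDX1, FTL and FTH1.

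HIF targets rose with glycolysis genes (r = 0.838, permutation p = 0.00171, adjusted p = 0.0233; rho = 0.879, permutation p = 0.00161; n = 10). Genes of the glycolysis list such as SLC2A1, PGK1 and LDHA are also known HIF targets, so the 2 scores are not independent by design. Without the 2 tumours farthest from the median HIF score, 1 and 5, r was 0.697 (exact permutation p = 0.0545), so the call rests on those tumours but the size of r does not. It was 0.847 within the 7 tumours, which leave out both (exact permutation test, adjusted p = 0.0600) and 0.575 given the share outside genes (permutation test, adjusted p = 0.219). With 1 tumour left out r was between 0.782 and 0.924 for both relations, but neither passed without tumour 2 (adjusted p = 0.0620 for both), 3 (0.0825 for both), 4 (0.0995 for glutathione and NRF2, 0.0553 for HIF and glycolysis), 5 (0.0804 and 0.0764), 9 (0.0596 for both) or 10 (0.0701 for both), and HIF and glycolysis did not without tumour 1 (0.0877), by the exact permutation test. The other 20 relations did not pass, with r between -0.673 and 0.783. TCA cycle and nuclear oxidative phosphorylation genes had r = 0.783 (permutation test, adjusted p = 0.0607), and 0.926 within the 7 tumours (exact permutation test, adjusted p = 0.0327). That relation passed without tumour 7 (exact permutation test, adjusted p = 0.000970), NRF2 targets with the pentose phosphate list without tumour 1 (0.0114), and T cells with B and plasma cells without tumour 6 (0.0206). The glutathione synthesis score had r = 0.399 with HIF targets, 0.545 with glutathione use and -0.0453 with the gamma-glutamyl cycle (permutation test, adjusted p = 0.395, 0.208 and 0.904).

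**Figure D4:**
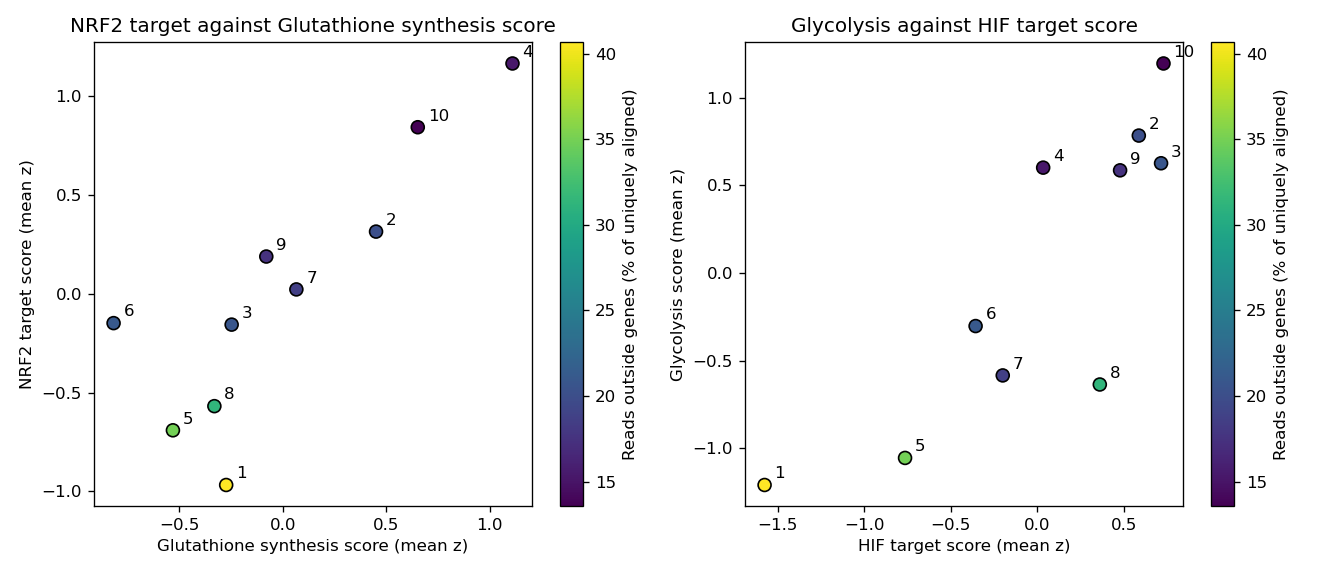
NRF2 target score against glutathione synthesis score (left) and glycolysis score against HIF target score (right), both as mean z-scores, with 1 numbered point per tumour coloured by the percent of uniquely aligned reads outside genes. The r is 0.844 on the left and 0.838 on the right, and tumours 1, 5 and 8 have negative values on both vertical axes.

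APCS, which encodes serum amyloid P, was the 1 gene of 21224 past the threshold against the glutathione synthesis score by edgeR (negative slope, adjusted p = 0.0264, r = -0.547). Nearly all its reads were in tumour 6, where log2 CPM was 7.42 against a median of -3.72, near the floor set by the prior count. The call thus sets 1 library against counts near 0, and the size of its slope is not interpretable. At an unadjusted p under 0.05 there were 3279 genes; limma-voom gave 0 past the adjusted threshold and DESeq2 853. The edgeR count was 0 without tumour 1, 6, 7 or 8 and 2 without tumour 9, and without tumour 4 the 1 gene was not APCS. The positive slopes of smallest p, not past the threshold, were those of FTLP3, a ferritin pseudogene (0.97, SE 0.126, adjusted p = 0.0676), EGR3, PLBD1, JAKMIP2 and TFPI2.

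Against the HIF target score, 5 genes rose and 25 fell of 21212 tested by edgeR. PLIN2 rose by 1.53 log2 units per SD of score (SE 0.231, adjusted p = 0.0354), SLC39A14, a metal transporter, by 1.38 (SE 0.215, adjusted p = 0.0398) and SLC2A5, a fructose transporter, by 1.41 (SE 0.238, adjusted p = 0.0499); RIPK4 and PCDHB14 also rose. Genes that fell included NPHS1, which is expressed in podocytes, and TMEM213, GGT6 and FOXJ1. The last 3 had low levels, with means of 1.29, 0.735 and 0.447 CPM, and NPHS1 averaged 0.360 CPM without tumour 1. Of 16 glycolysis genes, 14 rose when adjusted over the list alone, against 0 over all genes tested. The count of 30 was 0 without tumour 1, 4 or 9, 11 without tumour 5, 13 without tumour 7 and 1066 without tumour 8. It was 0 with the share of reads outside genes as a second term (1538 at an unadjusted p under 0.05) and 0 within the 7 tumours of low share (1033), by edgeR. With that term the 5 rising genes had slopes of 0.935 to 1.27, against 1.01 to 1.53 without it. Slopes were -3.21 against -3.01 for TMEM213, -2.54 against -2.74 for GGT6, -2.17 against -2.27 for FOXJ1 and -1.94 against -2.62 for NPHS1. Over the 10 tumours without that term limma-voom gave 154 genes (25 positive, 129 negative) and DESeq2 1370 (705 positive, 665 negative). The lean towards falling genes thus depends on the tool.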

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

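Of 154 values per tumour screened for 1 tumour far from the other 9, 12 stood apart, where chance alone gives about 1 in 20; the genes screened were listed after values were seen. The test of kidney cortex was chosen after its result was seen, and the test of glomeruli before.

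Tumour 1 stood above the other 9 in the other nephron score (1.39), the 3p tumour suppressor score (1.60), and log2 CPM of NPHS1 (6.19) and VHL (5.61). It was lowest in log2 CPM of GSTA1 (1.93). NPHS1, a gene of podocytes, the filter cells of the glomerulus, is among the genes that fell with the HIF target score, and that count was 0 without tumour 1, but also 0 without tumour 4 or 9. Normal cortex in that piece cannot be told apart. The proximal tubule score was -0.622 in tumour 1, which met the prediction written against cortex, a score below 0. A further requirement, not part of that prediction, held the verdict open. It asked for the lowest score of the 10 tumours, which tumour 5 had (-0.823). Members of the list differed. SLC34A1 (0.295 CPM) and SLC22A6 (0.147 CPM) were low in tumour 1, while SLC5A2 (5.21 CPM) was highest there, all picked after their values were seen. AQP1 ranged from 85.9 to 1189 CPM over the tumours, a baseline that would hide a small share of cortex in that gene. SLC34A1 and SLC22A6 had no such baseline in tumour 1. Glomeruli may be present and stay open: 5 of 8 other podocyte genes (PTPRO, WT1, PLA2R1, CLIC5 and TCF21) were highest there, between the bounds of 2 and 6 set beforehand, while PODXL, SYNPO and PODN were highest in tumour 9; no biological explanation was tested.

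The share of reads in more than 1 gene was highest in tumour 2, at 9.15%, as was log2 CPM of IGJ, the joining chain of antibodies (8.21). Tumour 3 had the lowest stroma score (-1.69) and the lowest log2 CPM of NNMT (8.02). Log2 CPM was highest for APCS in tumour 6 (7.42), for AKR1B10 in tumour 7 (2.97) and for ACADVL in tumour 8 (11.22).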

How the results depend on the processing

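No paired analysis was possible because the labels give 1 group and no shared numbers. Of 2603 alternative values for 136 results, 2267 kept direction and side of the threshold (counts: stayed within 1.5 times), 229 became weaker, 75 stronger and 32 turned direction, none of the last past the threshold. The 7 tumours, the share and macrophage terms and the correlated random lists were chosen after the data were seen. Unless a setting has fewer genes or tumours, the cause was not tested. With 10 tumours, slopes of 0.5 log2 units per SD were not recovered in simulated data.

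Counts of pairs (18 to 22, against 19), variable lists (9 to 16, against 13) and coherent lists (19 to 24, against 23) stayed within 1.5 times; 5 variable and 16 coherent lists passed in each of 19 alternatives. Relations past the threshold, 2, numbered 4 with library totals only, 1 given log2 library total, 7 given the proximal tubule score, 0 without tumour 2, 3, 4, 5, 9 or 10, and 2 or 3 without any other. The r of glutathione synthesis and NRF2 targets was 0.782 to 0.911 without single tumours and 0.743 given the macrophage score. That of HIF targets and glycolysis was 0.788 to 0.924 without single tumours, 0.847 within the 7 tumours, 0.737 given log2 library total and 0.575 given the share.

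Genes on the glutathione score, 1, numbered 0 with library totals only, limma-voom, the proximal tubule, library total or macrophage term, the unscaled score and the 7 tumours, 2 without a filter, 853 with DESeq2, 0 without tumour 1, 6, 7 or 8, and 2 without tumour 9. Genes on the HIF score, 30, numbered 19 with DESeq2 size factors, 130 without a filter, 0 at a mean count of 50, 1370 with DESeq2, 154 with limma-voom, 1 with the proximal tubule term, 0 with the library total or share term and in the 7 tumours, 54 with the macrophage term, and, without tumour 1, 4 or 9, 0, without 5, 11, without 7, 13, and without 8, 1066.

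Direction turned for these r: glutathione synthesis with the gamma-glutamyl cycle, 0.0202 without a filter, 0.0467 in the 7 tumours and -0.145 to 0.308 without single tumours; with proximal tubule, 0.0182 by Spearman and 0.248 given macrophages; with HIF targets, -0.0707 given the share. For HIF targets and endothelium it was -0.371 given library total and -0.138 given the share, for oxidative phosphorylation and mitochondrial genes 0.362 in the 7 tumours, and for fatty acid oxidation and lipid storage -0.152 given the share. T cells and antigen presentation gave 0.157 with library totals only, 0.293 given library total, 0.445 given the share and -0.372 to 0.0152 without single tumours. Stroma and endothelium gave 0.0486 given library total and 0.263 given proximal tubule.

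Among log2 ratios, GCLC/GCLM turned to 0.26 without length correction and 0.0925 in the 7 tumours, and GSTP1/GSTA1 to -0.00667 in the 7 tumours. Without single tumours MTHFD2/MTHFD1 ranged from -0.26 to 0.0203 and CA9/CA12 from -0.19 to 0.205, with 0.337 in the 7 tumours. The mean correlation of the gamma-glutamyl cycle ranged from -0.0612 to 0.0152 without single tumours, was 0.0427 without the first component and 0.0429 given the share, and moved above that of random lists in the last 2.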

Other observations

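On the glutathione synthesis score, 6 of 16 lipid storage and synthesis genes passed when adjusted over the list alone and 0 over all genes tested (edgeR quasi-likelihood test), 5 upward and 1, FABP7, downward. FABP7 stood at 515 CPM in tumour 6, which had the lowest glutathione synthesis score (-0.818), and averaged 4.96 CPM without that tumour. All 13 macrophage genes tested had positive slopes, and 3 passed over the list alone (0 over all genes); these were CD163, MSR1 and FCER1G, the last 2 named after their values were seen. None of the 15 T and cytotoxic cell genes passed, and all had negative slopes. On the HIF target score, 7 of 12 immediate early genes passed over the list alone, all upward (0 over all genes).

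Among genes with a mean of at least 10 CPM, FGB, which encodes a chain of fibrinogen, had the largest variance for its level, ranging from 0.0802 to 697 CPM. LBP, which binds bacterial lipopolysaccharide, ranged from 0.0802 to 3839 CPM and was highest in tumour 10. The 15 most variable also held FGG, FGA, SAA1, SLC17A3 and LTF.

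The tests below of nuclear RNA, of the share of reads outside genes, of macrophage RNA and of the order of the tumours were chosen after related values were seen, as was the requirement that the verdicts on genomic DNA, the share and macrophage RNA hold with each tumour left out.

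The first principal component followed the share of reads outside genes, which may include reads in introns. Such reads could not be counted apart. Depth is argued against: with each library thinned to 21539248 gene counts the absolute r was 0.971. Nuclear RNA may take a larger part of tumours 1, 5 and 8. Over 5 RNAs taken as nuclear the median r with the share was 0.806, above 99.8% of random sets of 5 genes. The r was 0.806 for NEAT1, 0.878 for TUG1 and 0.890 for MEG3. It was 0.470 for KCNQ1OT1 and 0.541 for OIP5-AS1 (permutation p = 0.171 and 0.104). Whether these RNAs were confined to the nucleus was not tested. Genomic DNA cannot be told apart: olfactory receptor reads rose by 24.9% of what even coverage of the genome would add, but by -11.1%, 64.7% and 28.8% in tumours 1, 5 and 8, and by 3.64% without tumour 5 23.7% without tumour 8 and 50% without tumour 1. No biological explanation was tested.

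Glutathione synthesis and NRF2 target scores rose together. The share of reads outside genes as the whole cause is argued against by a partial r of 0.887, between 0.817 and 0.937 with each tumour left out. Macrophage RNA cannot be told apart. Without FTL, FTH1 and HMOX1 the partial r given the macrophage score was 0.689 (permutation p = 0.0303), as low as 0.501 without tumour 5. These values met the prediction written against macrophage RNA. A further requirement, not part of that prediction, was not met: with all members the adjusted p was 0.0614 (permutation test). The macrophage score, whose C1QB and C1QA averaged 496 and 467 CPM, had r = 0.656 with the glutathione score (permutation p = 0.0392). No biological explanation was tested.

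For the 1 gene called on the glutathione score, chance order of the tumours cannot be excluded: 24 of 100 orders, the real one included, gave at least 1 gene. The highest other gave 260, which points to structure among the samples, though its cause was not tested. In the first 41 orders 9 gave at least 1 gene, with a highest other of 2. For the 30 genes on the HIF target score 2 of 100 orders gave as many, the real one included, and the highest other gave 39. In the first 41 orders these were 2 and 39. So many calls were rare among chance orders. Chance order is not excluded, since another order gave more genes and further orders were drawn after the first were seen. These counts cover the 10 tumours together, since the real count was 0 without tumour 1, 4 or 9, 11 without 5, 13 without 7 and 1066 without 8.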
